A study of Mus musculus with 6 samples.

How the data were processed

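The samples were mouse induced pluripotent stem (iPS) cells that lack Nac1, the gene also named Nacc1, and that received human NAC1 (hNAC1). Cells of 2 null clones, clone 5 and clone 7, were taken on days 0, 2 and 5 of the rescue, which gave 1 array per clone and day and 2 arrays per day. All 6 arrays lay on 1 Illumina mouse bead chip with 45281 probes, so no chip batch could separate them. The 2 replicates of a day are 2 different clones, and no culture of a clone was repeated on a day. The p-values of the day comparisons therefore rest on how far the changes of the 2 clones differ, and those of the clone comparison on how far the difference between the clones varies over days.

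The deposited probe table holds the average bead signal of each probe as an intensity that the authors neither normalised nor corrected for background, with a median of 93.4 to 95.9 and a highest value of 17019 to 19172 per array. The same deposited table gives a detection p-value of each probe against the negative controls of its array. The deposited series values are on a log2 scale after background subtraction and normalization between arrays by the authors, and 15401 to 15441 cells per array are empty. The authors' fold change table, also deposited, lists log2 values of 698 probes, their log2 fold change between day averages, and an unadjusted p-value that equals an unpaired test of 2 against 2 arrays. Its probes changed at least 2-fold between day 0 and day 5 with a p-value of up to 0.05. The software behind these files is not given in the sources used here. Probe symbols were matched to current names with a RefSeq gene table of the GRCm38.p6 assembly, which was also used for the chromosome of each gene. Of the probes, 35777 had a current symbol, 8037 of them through a synonym, and 9504 kept the name in the deposited table.

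Signals were background corrected with the normexp model from the detection p-values, with an offset of 16, quantile normalised and put on a log2 scale with limma 3.58.1 in R 4.3.3. Probes with a detection p-value under 0.05 on both arrays of at least 1 day were kept (17471 probes). For each gene, the probe with the highest mean was used, which left 12030 genes. A linear model with day and clone was fitted to each gene with limma (lmFit and eBayes, 2 residual degrees of freedom, 5.24 prior degrees of freedom), so that days were compared within clones and clones within days. Clone entered the model because the design samples the same days in each clone. Across genes, the deviations from the day means correlated at 0.36 between day 0 and day 2, -0.07 between day 0 and day 5 and 0.34 between day 2 and day 5. Genes passed at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The standard errors (SE) given are those of the fit. A fold against a day on which no array detected the probe is a lower bound, taken against the lowest detected value. The number of arrays limits the precision of every value.

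The comparisons, the tests, 22 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Lists with at least 5 measured members, 20 of them, were tested with camera at a preset correlation of 0.01 and adjusted over these lists. Camera with an estimated correlation and fry were run beside it. The estimated form rests on the 2 residual degrees of freedom and has little power. A call lost with it is therefore not shown to be due to correlation between genes. Named genes are Nacc1, Zeb1, Cdh1, Pou5f1, Nanog, Sox2, Klf4 and Myc, the 8 higher and 8 lower genes of each day comparison that had the largest change in the clone that changed less, and up to 4 members with the largest mean change of each list described. Between clones, 6 genes higher and 6 lower on all 3 days are named, and from the authors' table the 5 largest changes each way. Other named genes are said to be chosen after their values were seen. Changes on day 2 and day 5 were not set against each other, because they share the day 0 arrays.

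The procedure was tested on simulated data of the same size in which 200 genes were changed. It recovered 84% to 92% of genes changed 2-fold and 100% of genes changed 4-fold between days. False calls were 27 of 219 calls for day 2 against 0, 14 of 198 for day 5 against 0 and 15 of 200 for day 5 against 2. Each of these shares is above the adjusted p set for passing. The clone comparison had 28 false calls, and data without change gave 1 to 8 calls between days. On the real arrays Col18a1, Mmp2 and Nid1 were 4.99-fold, 4.81-fold and 4.24-fold lower on day 2 and did not pass. The simulated recovery may therefore not hold for the real data. Alternatives were no clone block, clone as a random block (with statmod 1.5.0), no background correction, an offset of 50, median scaling, the series values, no detection filter, detection at p under 0.01 on all 6 arrays, every probe or the mean of probes, trended and robust variance shrinkage, a threshold of 0.1, only the 4 arrays compared, and each array left out in turn. The unpaired test of the authors' table, the clones without chromosome 1 and the change of the clone difference over days were added after the data were seen. The unpaired test, with 2 against 2 arrays, has little power after adjustment over all genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The values of some list members are not reported here. Probe positions are not reported, since the deposited files name no genome build.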

Results

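Gene expression was measured on 6 bead arrays in mouse iPS cells without Nac1, before and during rescue with human NAC1. Clone 5 and clone 7 were each sampled on days 0, 2 and 5, with 1 array per clone and day (n = 2 arrays per day). Between 16739 and 18150 of the 45281 probes were detected on an array, which is 37.0% to 40.1%, and 12030 genes were tested. NAC1 is a nuclear BTB-domain protein of pluripotent cells, and the rescue asks which mouse genes respond when it is returned. No cells without the rescue were sampled over the same days. A change between days therefore cannot be told apart from time in culture or the handling of a day. The probes of mouse Nacc1 cannot check the sample labels, since the rescue gene is human and the position of the probe relative to the deletion is not known. The Nacc1 probe read 0.06 ± 0.17 (SE) higher on day 2 than on day 0 and -0.24 ± 0.17 on day 5 on the log2 scale, and neither value passed the test. This probe was detected on all 6 arrays, day 0 included, at log2 values from 6.87 to 7.34, and of the 3 other probes, 1 was also detected on all 6 arrays, 1 on 3 and 1 on 0.

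Day 5 was compared with day 0 to find genes that differ after the longest rescue. The proton pump subunit gene Atp12a, undetected on day 0, rose at least 7.53-fold, and Dppa3, a gene of the early embryo and germ line, rose 5.81-fold (log2 2.54 ± 0.17 SE, adjusted p = 0.00194). The gene of the receptor tyrosine kinase Kit rose 5.90-fold and the cytoskeletal adaptor gene Tes rose 5.99-fold. Slc32a1, which encodes the vesicular transporter of GABA and glycine, fell by 4.35 ± 0.24 (SE) on the log2 scale (20.4-fold, adjusted p = 0.00194). The basement membrane genes Col18a1 and Nid1 fell by 3.24 ± 0.21 and 2.63 ± 0.20. In all, 512 genes passed, 296 higher and 216 lower, each in the same direction in both clones, with a median absolute log2 change of 1.16. The shared direction is not a separate result, because the test rests on the difference between the clones. A gene whose clones changed in opposite directions could not have passed it. The larger number of higher genes depended on the processing. It was 146 higher and 155 lower with detection on all 6 arrays, and 62 and 65 without background correction. Median scaling gave 320 higher and 167 lower, and the fit without the clone block 120 and 88.

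The other genes ranked highest by the clone that changed less were Gadd45g, a growth arrest gene, with a rise of 2.81 on the log2 scale, Cabs1 with 2.62, Smco2 with 2.93 and Plac8 with 3.33. Smco2 was detected on 1 of the 2 day 0 arrays. The other genes ranked lowest were Pla1a, which encodes a phospholipase and fell by 3.38, Gcnt3, which encodes a glycosyltransferase and fell by 3.40, Endod1 (-3.11), Dlgap1 (-2.84) and the serine protease gene Htra1 (-2.44). Their adjusted p-values were between 0.00194 and 0.0247. On other probes the changes were smaller, at 0.85 for Kit, -2.58 and -1.15 for Col18a1, and -2.35, -1.15 and -0.75 for Dlgap1.

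**Figure D1:**
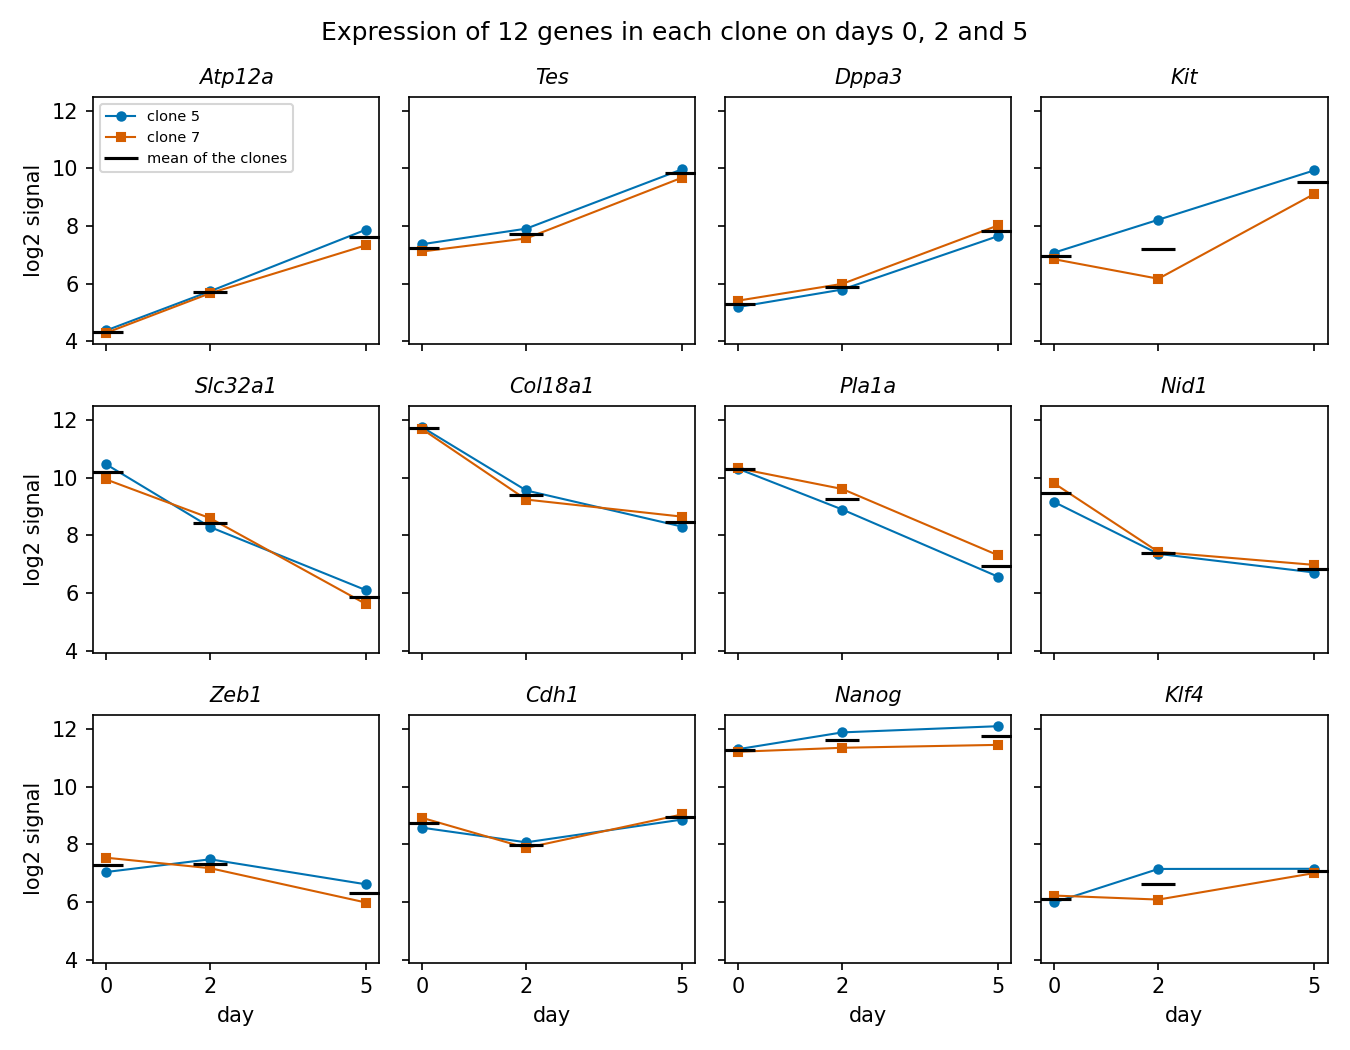
Log2 signal (vertical axis) of 12 genes against day (horizontal axis), with 1 point per array, lines joining the arrays of a clone and a bar at the mean of both clones. Slc32a1, Col18a1, Pla1a and Nid1 were lower on day 5 than on day 0 in both clones, and Zeb1, Cdh1, Nanog and Klf4 did not pass the test.

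Among the genes fixed for this study, Zeb1, which encodes a repressor of epithelial genes, had a log2 change of -0.99 ± 0.27 (SE) on day 5, -0.43 in clone 5 and -1.56 in clone 7 (adjusted p = 0.0956). Cdh1, which encodes E-cadherin, had a change of 0.20 ± 0.19 (adjusted p = 0.606). The pluripotency factor genes had changes of -0.66 for Pou5f1, 0.52 for Nanog, -0.40 for Sox2 and 0.97 for Klf4, and none of them passed (adjusted p from 0.113 to 0.217). Myc was not tested, because 1 of its 2 probes was detected on 2 of the 6 arrays and the other on 0.

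Of 32 measured genes of the pluripotency network, 1 rose and 3 fell. Besides Dppa3, these were Gbx2 (-2.66) and Klf5 (-1.54), both genes of transcription factors of naive pluripotency, and Tfcp2l1 (-1.05), which is named after its value was seen. Fbxo15, at 1.24, did not pass. Adjusted over the list alone, 9 passed. The list as a whole had a median of -0.09 and did not pass (adjusted p = 0.263).

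Of 23 epithelial genes, 3 rose and 0 fell by limma, with 18 members above 0 and 5 below. The 3 were Esrp1 (1.49 ± 0.23 SE), a splicing regulator of epithelial cells, Cdh3 (1.38 ± 0.17), which encodes P-cadherin, and Marveld3 (0.99 ± 0.20), a tight junction gene, while Pkp3 was at -0.82 and did not pass. The list had a median of 0.33 and moved up against other genes (adjusted p = 0.0169). With an estimated correlation it did not pass (adjusted p = 0.591 with an estimated correlation). Of 11 mesenchymal genes, 3 fell and 1 rose: Mmp2 (-2.33) and Mmp14 (-0.84, named after its value was seen), which encode matrix metalloproteases, and Vim (-1.40), which encodes vimentin, fell, and Tgfb1, undetected on day 0, rose at least 1.74-fold. Adjusted over the list alone, 7 of the mesenchymal genes and 3 of the epithelial genes passed. The mesenchymal list had a median of -0.73 and did not pass (adjusted p = 0.0636).

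The germline list moved up on day 5, with all 8 measured members above 0, a median of 0.64 and an adjusted p of 0.00463 at the preset correlation. Tdrkh, a gene of the piRNA pathway, rose by 1.69 ± 0.17 (SE) by the probe used, with 0.52 by its other probe, and Taf7l (0.98), Tuba3a (0.79) and Piwil2 (0.68) did not pass. Adjusted over the list alone, 4 passed. The interferon response list moved down, with 6 of 7 measured members below 0 and a median of -0.41 (adjusted p = 0.0169). Of its 20 genes 13 were not measured, among them Ifit1, Irf7 and Rsad2, so the call covers a part of this response. Ifi35 fell by 1.20, and Ifitm3 (-1.26) and Ddx58 (-0.41) did not pass. The lists of p53 targets (17 measured) and of the cell cycle (21 measured) had medians of -0.22 and -0.20 and moved down (adjusted p = 0.0388 each). Of these genes only Gadd45a fell, by 1.74, and Plk2 (-0.65), Tyms (-0.64) and Rrm2 (-0.62) did not pass. All 4 calls of this paragraph were lost with an estimated correlation (adjusted p = 0.591 with an estimated correlation for each). The estimated correlations of the interferon and p53 lists were -0.15 and 0.0045, below the preset 0.01. Correlation between genes therefore does not account for the loss of these calls.

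The remaining lists did not pass on day 5. Cholesterol synthesis genes had a median of 0.33 (adjusted p = 0.0504). Glycolysis and hypoxia genes had a median of 0.29 (adjusted p = 0.0636), and Ndrg1, at 1.86, did not pass. Lineage lists held a few passing members: Gata6, a primitive endoderm gene undetected on day 0, rose at least 2.07-fold, Tead4 (-1.32), a trophectoderm gene, fell, Gsc (1.20), 1 of 3 measured mesendoderm genes, rose, and the primed epiblast gene Dusp6, a target of FGF and ERK signalling, fell by 1.84. Peg3 (-1.52) fell and Dlk1 (1.98) rose among imprinted genes. On other probes Peg3 was at -0.79 and -1.41, Dlk1 at 1.66 and Dusp6 at -1.95 and -1.06. Median changes were 0.72 for neuroectoderm, 0.20 for fibroblast and matrix, -0.21 for DNA methylation and Polycomb, -0.00 for contractile and actin cytoskeleton, -0.05 for immediate early and heat shock, 0.05 for the unfolded protein and amino acid response and 0.02 for reference genes. The 3 measured genes of macrophages and blood had a median of 0.13 and were too few to test. Median, mean and test differed in sign on day 5 for the imprinted, fibroblast and matrix, contractile and primitive endoderm lists, none of which passed.

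**Figure D2:**
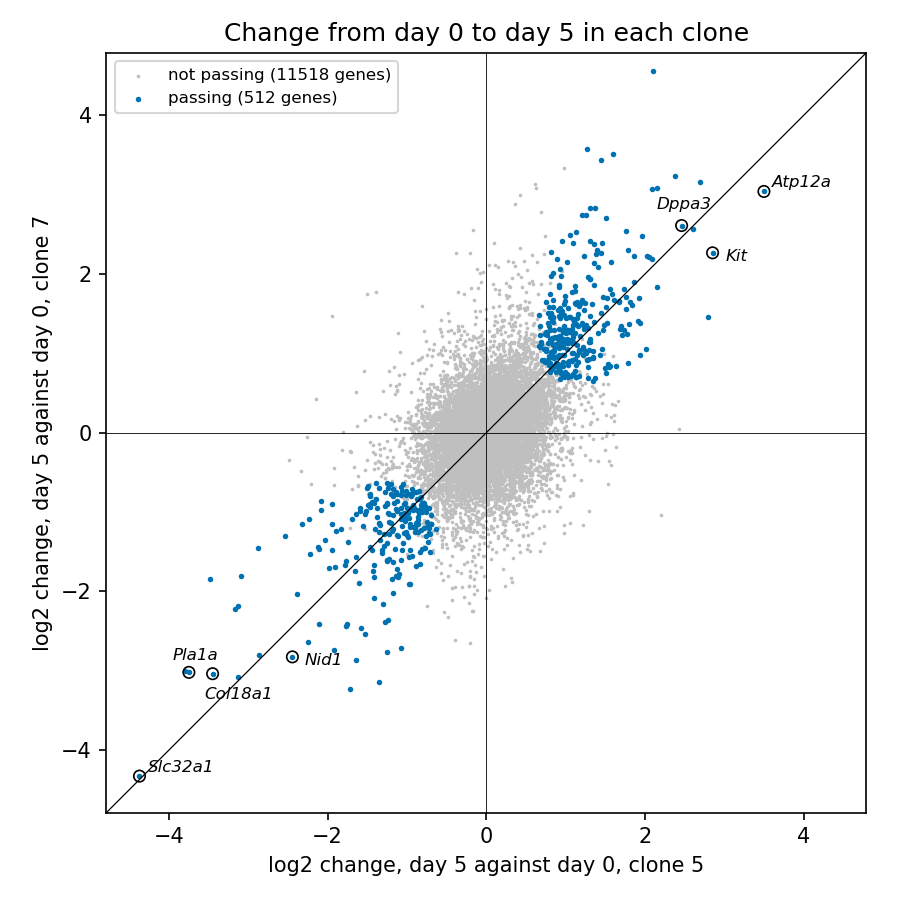
Log2 change from day 0 to day 5 of each of 12030 genes in clone 5 (horizontal axis) and clone 7 (vertical axis), with the 512 passing genes in blue, the line of equal change in black and 7 genes circled. All passing genes lie in the 2 quadrants where both clones changed the same way, which the test requires of a passing gene.

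The changes of the clones correlated across genes at a Pearson r of 0.46 and a Spearman rho of 0.35, where genes are not independent replicates. At least 2-fold, 248 genes changed the same way in both clones, 143 higher and 105 lower, and 8 changed in opposite directions. Without clone in the model, 208 genes passed instead of 512, and no gene passed by limma with the series values (2162 at an unadjusted p under 0.05) or without the detection filter (3742), or by the unpaired test of the authors' table (1258). The count fell to 138 without the day 0 array of clone 7 and to 250 without the day 5 array of clone 7, and the test over any day called 300 genes.

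Day 2 was compared with day 0 to find early changes, and no gene passed. The genes with the lowest adjusted p were Col18a1 (log2 change -2.32 ± 0.21 SE), Nid1 (-2.09 ± 0.20) and the matrix metalloprotease gene Mmp2 (-2.27 ± 0.22), at 0.0622 each, and each was lower in both clones. Other probes were at -1.92 and -0.81 for Col18a1 and at -0.85 for Nid1. The amino acid transporter gene Slc38a5 was at -2.12, Slc32a1 at -1.76, Porcn, which encodes an acyltransferase of Wnt proteins, at -1.68, Htra1 at -1.55 and Gbx2 at -1.26. The genes ranked highest were P2rx7 (1.75), which encodes an ATP-gated channel and whose other probes were at 0.75 and 0.20, Cabs1 (1.46), Rassf1 (1.35), Ccdc137 (1.30), Stk19 (1.12), Zfp27 (1.09), Rad9a (1.06) and Atp12a, which was at least 2.01-fold higher. Cdh1 was at -0.77 ± 0.19 (SE) and Zeb1 at 0.04 ± 0.27, and values were -0.29 for Pou5f1, 0.36 for Nanog, -0.07 for Sox2 and 0.51 for Klf4.

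As groups, 5 lists moved down on day 2 at the preset correlation, and none with an estimated correlation (adjusted p = 0.599 with an estimated correlation for 4 of them and 0.619 for primitive endoderm). The unfolded protein and amino acid response list had 11 of 13 members below 0 and a median of -0.60 (adjusted p = 2.5e-05), with Chac1 at -1.49, the chaperone gene Hsp90b1 at -1.40, Pdia4 at -1.27 and Phgdh at -0.91. Adjusted over the list alone, 7 of them passed. Fibroblast and matrix genes had a median of -1.05 (adjusted p = 0.0142), with Thy1 at -1.32, Fstl1 at -1.23, Sparc at -1.20 and Col5a1 at -1.05. Of the 22 genes of this list 7 were measured, and Col1a1 and Col3a1 were not. Primitive endoderm genes had a median of -0.33 (adjusted p = 0.0101), led by the basement membrane collagen gene Col4a1 (-1.40), by Apoe (-1.28) and by the collagen gene Col4a2, which was undetected on day 2 and at least 2.00-fold lower. Here 9 of 19 genes were measured, and Gata4 and Sox17 were not. Imprinted genes had a median of -0.31 (adjusted p = 0.0101) and mesenchymal genes of -0.06 (adjusted p = 0.0396), with Vim at -1.19 and Fn1 at -0.99. Other probes of Fn1 were at -0.58, -0.18 and -0.63. A list of 28 measured membrane and lysosome genes, written after the data were examined, had a median of -0.22 in clone 5 and -0.60 in clone 7 on the same day. The pluripotency list had a median of -0.02 and the epithelial list of -0.15, and neither passed (adjusted p = 0.955 and 0.418).

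The limma test of day 2 called 0 of 12030 genes, with 1630 at an unadjusted p under 0.05, and the unpaired test of the authors' table also called 0, with 922. Without clone in the model 0 passed, with trended and robust shrinkage 3 passed, and without either day 5 array or both, 17 passed. Across genes the changes of the clones had a Pearson r of 0.41 and a Spearman rho of 0.37. At least 2-fold, 44 genes changed the same way in both clones, 14 higher and 30 lower (22 and 22 with median scaling), and 0 in opposite directions.

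Day 5 was compared with day 2 to find later changes. Tes rose by 2.09 ± 0.16 (SE), Dppa3 by 1.94 ± 0.17 and Tdrkh by 1.87 ± 0.17 on the log2 scale (adjusted p = 0.016 each). The lipoxygenase gene Alox12b rose 5.66-fold, the imprinted gene Dlk1 by 2.60 on the log2 scale, Gadd45g by 2.15 and Pdpn, which encodes podoplanin, by 1.84. Pla1a fell by 2.32 ± 0.22, Slc32a1 by 2.59 ± 0.24, Dlgap1 by 2.20 ± 0.20 and Phlda1 by 1.87 ± 0.18. Gcnt3 (-2.25), Lpar6 (-1.85) and Cyria (-1.73) also fell, and Unc45b, undetected on day 5, fell at least 3.86-fold. In all, 95 genes passed, 71 higher and 24 lower.

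Cntnap2 rose by 2.29 from day 2 to day 5 by the probe used, and its other probe was at 0.22. Other probes were at 0.53 for Tdrkh and at -1.76, -0.88 and -0.49 for Dlgap1. Cdh1 was at 0.98 ± 0.19 (SE, adjusted p = 0.069) and Zeb1 at -1.03 ± 0.27 (adjusted p = 0.118), and neither passed. At the preset correlation 8 lists moved up and 0 moved down, and all 8 were lost with an estimated correlation (lowest adjusted p = 0.474 with an estimated correlation). The germline list had 8 of 8 members above 0 and a median of 1.12 (adjusted p = 6.43e-06), with rises of Tdrkh and Tuba3a (1.48). The unfolded protein and amino acid response had 11 of 13 members above 0 and a median of 0.64 (adjusted p = 7.99e-05), with a rise of Phgdh, an enzyme gene of serine synthesis, by 1.89. The epithelial list had a median of 0.53 (adjusted p = 0.000357), with a rise of Cdh3 by 1.38. Medians were 0.57 for fibroblast and matrix, 0.35 for cholesterol synthesis, 0.44 for primitive endoderm, 0.24 for glycolysis and hypoxia and 0.58 for imprinted genes, with adjusted p from 0.00361 to 0.0343. The membrane and lysosome list written after the data were examined had medians of 0.29 in clone 5 and 0.48 in clone 7. Adjusted over the list alone, 7 germline, 8 unfolded protein and 11 epithelial genes passed. This comparison shares the day 2 arrays with day 2 against day 0, so a list low on day 2 tends to rise here. The unfolded protein, fibroblast and matrix, primitive endoderm and imprinted lists moved down there and up here. Their medians on day 5 against day 0 were 0.05, 0.20, 0.03 and -0.07, and none of them passed.

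**Figure D3:**
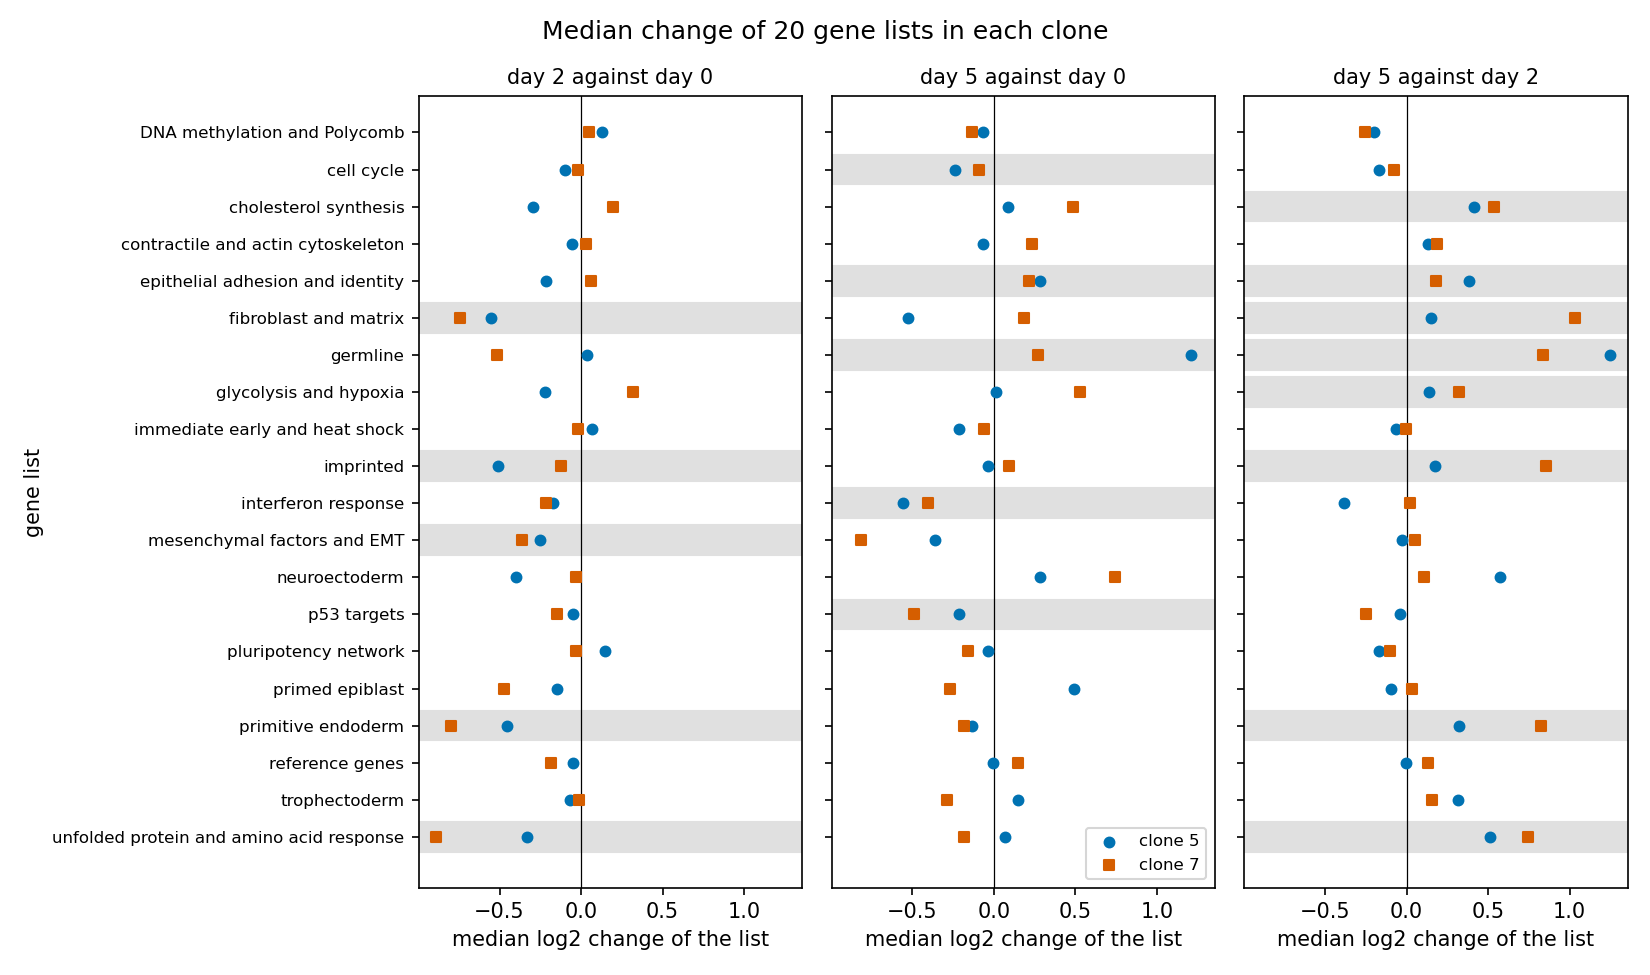
Median log2 change (horizontal axis) of 20 gene lists (vertical axis) in clone 5 (circles) and clone 7 (squares) for the 3 comparisons of days, with grey bands for lists that passed at the preset correlation. The 5 lists passing on day 2 had medians below 0 in both clones, and the 8 passing from day 2 to day 5 had medians above 0 in both. These comparisons share the day 2 arrays.

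Without clone in the model 13 genes passed from day 2 to day 5, with no background correction 1, and with the series values or no detection filter 0 by limma (1781 and 3293 at an unadjusted p under 0.05). The count was 2 without the day 2 array of clone 5, 0 without that of clone 7, 41 without the day 5 array of clone 7, 516 without that of clone 5 and 329 without either day 0 array.

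Clone 7 was compared with clone 5 over the 3 days to describe how the lines themselves differ. No gene passed, and 12 had an adjusted p under 0.1, 8 higher and 4 lower in clone 7. Meg3, a maternally expressed imprinted RNA gene, was lower in clone 7 on all 3 days, at -1.97 ± 0.17 (SE, n = 3 arrays per clone) on the log2 scale or 3.92-fold (adjusted p = 0.0671). The matricellular protein gene Smoc1 was 4.44-fold higher in clone 7, Smtnl1 3.55-fold and the surface antigen gene Ly6a 3.38-fold, with Ube2l6, Rnf125 and Wdr45 between 2.40-fold and 2.70-fold. The mean of Ube2l6 in clone 5 was 4.58, below the lowest detected values of those arrays (4.59 to 4.70), so its fold is uncertain. The other lower genes under 0.1 were Gm5091 (-1.56), Wfdc2 (-1.34) and Syce1 (-1.10), the last named after its value was seen. Cpn1 (-1.22), Igsf21 (-1.19) and Stat4 (-1.07), also lower on all 3 days, had adjusted p-values from 0.102 to 0.109. Stat4 lies on chromosome 1, of which the 518 tested genes had a median of -0.34 in clone 7 against clone 5, a feature singled out after its values were seen.

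By lists, glycolysis and hypoxia genes were lower in clone 7, with 18 of 18 members below 0 and a median of -0.33 (adjusted p = 4.37e-06). Cholesterol synthesis (median -0.38, adjusted p = 0.0026), germline (-0.34, 0.00689) and fibroblast and matrix genes (-0.49, 0.0436) were also lower, and epithelial genes higher (0.11, 0.0363). All 5 calls were lost with an estimated correlation (adjusted p = 0.558 with an estimated correlation for each). Limma called 0 genes between clones, with 1356 at an unadjusted p under 0.05, and 0 genes whose clone difference changed steadily over days (755 at an unadjusted p under 0.05). Without day in the model 0 passed, with day as a random block 6, and without either day 5 array 79.

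The authors' table lists 698 probes for day 5 against day 0, 353 higher and 345 lower, all with an unadjusted p of up to 0.05 and a change of at least 2-fold. In the series values 749 probes met both bounds, so how the list was chosen is not fully known. It holds 628 symbols, of which 547 were tested here. Of these, 512 had the same direction here and 280 passed. The match was by symbol, and the fit used the probe with the highest mean. The values of a gene in the table and in the fit can therefore come from different probes. The largest log2 changes in the table were 5.62 for Nr5a2, 5.29 for Cd6, 4.87 for Abcc8, 4.53 for Chst7 and 4.52 for Rassf4, and -5.24 for Chga, -5.06 for Lypd5, -4.98 for Fsd2, -4.79 for Slc32a1 and -4.76 for Plekhg3. Nr5a2 had a day 0 average of -2.83 in that table and a change of 0.52 in the fit here, which did not pass. It was detected here on 2 day 0 arrays, so the fit may rest on another probe. The same holds for Chga and Plekhg3, with day 5 averages of -2.82 and -2.53 in that table and detection here on 2 day 5 arrays. For such genes, not passing here does not go against the table. Chga (-0.38), Plekhg3 (0.01) and Abcc8, undetected on day 0 and at least 1.29-fold higher, did not pass here either, and Fsd2 was not tested. Slc32a1 (-4.35) and Rassf4 (2.14, detected on 1 of the 2 day 0 arrays) passed, as did Cd6 and Chst7, undetected on day 0 and at least 3.45-fold and 2.12-fold higher, and Lypd5, undetected on day 5 and at least 5.51-fold lower. Over the 22261 probes with values on all 4 arrays, 1977 had an unadjusted p of up to 0.05 by the unpaired test whose p-values the authors' table lists, and 0 passed after Benjamini-Hochberg adjustment (lowest adjusted p 0.453). With 2 against 2 arrays this test could hardly pass a probe after adjustment, so the 0 does not show that the listed genes did not change. Limma on the series values also called 0 genes, with 2162 at an unadjusted p under 0.05.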

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

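The tests of fibroblast transcripts, of the day 2 array of clone 7, of the uncorrected signal on day 5 and of other groupings of the arrays were chosen only after the results they bear on were seen. The opposite changes below were not tested as differences between clones. From day 2 to day 5, Egr1, an immediate early gene, changed by -0.95 on the log2 scale in clone 5 and by 1.61 in clone 7. From day 0 to day 5, Ier3 changed by -0.81 in clone 5 and by 1.60 in clone 7. At least 1.5-fold, 87 of 12030 genes changed in opposite directions in the clones from day 0 to day 5, and 843 in the same direction.

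Genes of chromosome 1 were lower in clone 7 than in clone 5 on every day, with a median of -0.30 on day 0, -0.37 on day 2 and -0.37 on day 5, while the other chromosomes lay between -0.06 and 0.07 on these days. The authors' or the present normalization as the whole cause is argued against by the uncorrected signal, where chromosome 1 still lay -0.24 below the other chromosomes, and noise of dim probes by the brightest genes of the chromosome, at -0.43. All 10 consecutive segments of the chromosome were below -0.2, so a difference in copy number of the whole chromosome is a candidate explanation. It is a hypothesis, since DNA was not measured, the pattern was found and tested on the same data, and the log2 ratio of 3 to 2 copies would be 0.58. Which clone departs from the usual number cannot be read from these arrays.

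The fibroblast and matrix, primitive endoderm and unfolded protein and amino acid lists moved down on day 2 at the preset correlation only, with 20 of their 29 measured members lower in both clones and no gene past the limma test (1630 of 12030 genes at an unadjusted p under 0.05). Fibroblasts lost after day 0 are argued against by 6 of 6 abundant fibroblast transcripts with no probe detected on either day 0 array. A gene not detected is not shown to be absent, which limits this. The day 2 array of clone 7 alone is argued against by a median of -0.38 in clone 5. The lists were picked by a test that used clone 5 as well, so its median is not independent of that choice. A lower yield of all mRNAs translated at the endoplasmic reticulum stays open. Membrane and lysosome genes outside the pattern had a median of -0.22 in clone 5, between the bounds of -0.4 and -0.2 set for the test, and of -0.60 in clone 7, past the bound for this explanation, at percentiles 0.05 and 0 of random lists. Rescue with human NAC1, which the design varies with the day, also stays open and was not tested apart from it.

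On day 5, 7 genes known as targets of FGF or LIF signalling were lower in both clones, with a median of -1.69 (Dusp6, Etv1, Phlda1, Gbx2, Klf5, Tfcp2l1 and Irf1, chosen after their values were seen). A fall of all genes in their signal range is argued against by the uncorrected signal, where the 6950 genes of that range had a median of 0.0962 in clone 5 and -0.0224 in clone 7 (0.00203 over both after normalization), and the 7 genes -1.38 and -1.51. Lower FGF and ERK output stays open too. The test set for lower LIF and STAT3 output went against it in clone 7, with the limit given below. Other FGF and ERK targets lay at percentile 12.8 of random lists in clone 5 and 6.32 in clone 7, with 8 members lower and 3 higher in both clones, falls of Ets2 (-1.05) and Hbegf (-1.03), and Dusp4 (0.98) and Dusp14 (0.61) higher without passing. Other LIF and STAT3 targets lay at percentile 3.85 in clone 5 and 33.2 in clone 7. The value of clone 7 was past the bound of 25 that was set beforehand against this explanation. Socs2 (-0.84) and Il6st fell, and Icam1 (0.74) and Bcl3 (0.49) were higher without passing. With 7 members lower and 3 higher in both clones, a median near 0 cannot exclude a lower output for part of the targets.

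Between the clones, the real grouping of the 6 arrays gave 1356 genes at an unadjusted p under 0.05, and the highest of the other groupings gave 672. There are 10 groupings, too few for a share under 0.05. Groupings that put both arrays of a day on the same side use fewer arrays and are not a like comparison. Those that divided the arrays of every day, as the real one does, gave 672, 56 and 643.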

How the results depend on the processing

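The unpaired test of the authors' table and the clones without chromosome 1 genes were the alternatives here chosen only after the data were seen. Without chromosome 1 genes limma again called 0 genes between clones (1104 at an unadjusted p under 0.05). No passing result of a named gene reversed, although single genes were not followed with every probe, at a threshold of 0.1 or by the unpaired test, and no passing list reversed in the alternatives run for lists. Of 59 passing results for named genes, 56 kept passing with median scaling, 59 with trended and robust shrinkage, 43 with an offset of 50, 26 without the clone block, 20 without background correction, and 0 with the series values or without the detection filter. In the order day 5 against 0, day 5 against 2 and any day, counts were 512, 95 and 300, and became 208, 13 and 45 without the clone block, 318, 19 and 81 with clone as a random block, 127, 1 and 10 without background correction, 301, 38 and 128 with detection on all 6 arrays, and 1023, 437 and 804 at a threshold of 0.1. They were 0 for all 3 with the series values and without the detection filter, which tests 28908 genes, and 0 for day 5 against 0 by the unpaired test. Day 5 against 2 and any day also moved to 29 and 98 with an offset of 50, 61 and 144 with the mean of probes and 240 and 557 with trended and robust shrinkage, and day 5 against 2 to 329 on its 4 arrays alone. Day 2 against 0 moved from 0 to 3 with detection on all 6 arrays, trended and robust shrinkage or a threshold of 0.1, and to 17 on its 4 arrays. The clones moved from 0 to 6 with day as a random block, 1 with median scaling, 15 with trended and robust shrinkage and 12 at a threshold of 0.1. With 1 array left out, counts were 0 to 17 for day 2 against 0, 138 to 672 for day 5 against 0, 0 to 516 for day 5 against 2, 92 to 659 for any day and 0 to 79 for the clones. An array left alone on its day is assumed to vary like the others, and leaving out 1 array of a day not compared equals leaving out that day.

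Genes changed at least 2-fold the same way in both clones numbered 44 on day 2 and 248 on day 5, and became 11 and 54 without background correction, 13 and 89 with an offset of 50, 271 and 663 with the series values, and 147 on day 5 with detection on all 6 arrays. Lists passing became 0 in all 4 comparisons with an estimated correlation or fry. The estimated form has little power at 2 residual degrees of freedom. On day 2, 5 lists became 1 with the series values and 2 without the detection filter. On day 5 against 0, 5 became 8 without background correction and 3 with the series values. Between clones, 5 became 3 without the block, without background correction and without the detection filter. With 1 array left out, 4 to 7, 3 to 7, 4 to 9 and 1 to 5 lists passed on day 2, on day 5 against 0, on day 5 against 2 and between clones. Of those passing with all arrays, 1 of 5 on day 5 against 0 was still among the 3 without the day 5 array of clone 5, and 3 of 8 on day 5 against 2 among the 4 without that of clone 7. Except where stated, the cause was not tested. About 37.0% to 40.1% of probes stood above background, so a gene not detected here is not shown to be absent.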

Other observations

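Both tests of the X chromosome genes were chosen only after their values were seen. A stretch of 10 neighbouring genes on X, from Foxp3 to Otud5, had higher values in clone 7 than in clone 5, with a median log2 difference of 0.90 or 1.87-fold. It was 0.74 on day 0, 1.06 on day 2 and 0.91 on day 5. Wdr45 (1.43), Ccdc120 (1.40), Prickle3 (1.12), Plp2 (0.99) and Foxp3 (0.92) were the highest, and Syp (0.28) and Praf2 (0.35) the lowest. None of them passed the test between clones. In the first test run, the longest unbroken run above 0.5 in the stretch was 4 genes, no chromosome had a longer run, and 6 of 200 shuffled gene orders had a run as long. The stretch and the bound of 0.5 were both picked with the values in view, so that share does not measure how rare the stretch is. A second test was chosen after that result, with the ends of the stretch taken from the values. The highest median of any window of 10 neighbouring genes that shared no gene with the stretch was 0.45, and of the windows in 100 shuffled orders 0.46. Because the window was fitted to the stretch, that difference overstates how unusual the stretch is, and the stretch remains an observation.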
